A study of Mus musculus with 9 samples.

How the data were processed

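RNA-seq was measured in 9 libraries from mouse extra-embryonic endoderm stem (XEN) cells, a female line from a cross of M. m. molossinus with M. musculus. Total RNA was extracted with Trizol, and libraries were made with a stranded kit of 1 of 2 named makes. The labels do not say which make was used for which library, nor whether RNA was selected by poly(A) tail or depleted of ribosomal RNA. The libraries fall into wild type named WT_EV (n = 3), a paternal deletion upstream of Xist named DXp (n = 2), a homozygous deletion named DXp_DXm (n = 2), and wild-type clones named WT_clone (n = 2). What EV stands for, and the ends of the deleted segment, are not given in the sources used here. Per the labels each deletion had 2 biological replicates. The titles name both DXp libraries D1, both DXp_DXm libraries D3, and the WT_clone libraries clone 1 and clone 2. What D1 and D3 stand for is not given. If they name single lines, genotype and line cannot be told apart. Nothing in the labels says whether the WT_EV libraries came from separate cultures, so p-values measure only the spread between these samples.

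The authors checked reads with FastQC, aligned them with STAR 2.7.9a to GRCm38 (mm10) and counted reads per gene with featureCounts 2.0.1. The deposited tables hold raw read counts per gene, 1 table for the 7 WT_EV and deletion libraries and another for the 2 WT_clone libraries. The strand setting, the handling of reads that map to several places, and the annotation release are not given in the sources used here. The 7-library table lists 55401 genes, of which 55141 had a symbol and 54784 the same start and end in GENCODE M21, the reference used for symbols, biotypes, GC content and length. The WT_clone table was held in part: 11512 genes, with all 2626 genes of chromosome X, 3446 of chromosome 1, 3794 of chromosome 2 and 1646 of chromosome 3. Sums of the WT_clone columns are therefore not depths, and every comparison with WT_clone used the shared genes. Reads were not analysed here, so parental alleles were not told apart.

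Counts were filtered with filterByExpr, scaled by TMM and tested with the edgeR 4.0.16 quasi-likelihood test (robust) in R 4.3.3, with group as the model term and Benjamini-Hochberg adjustment over all genes tested. In the 7 libraries 15331 genes were tested and 40070 were not. In the 9 libraries 3302 shared genes were tested. A gene counted as changed at an adjusted p under 0.05, also counted with a change of at least 2-fold. Levels are TMM-scaled CPM (the count relative to the scaled library total), given as mean ± SD over libraries. The biological coefficient of variation was 33.7% in the 7 libraries. Intervals are 95% intervals unless named otherwise, from the SE of the fit and a t distribution with libraries minus groups as its degrees of freedom. They can be wider than the p of the edgeR test implies, since that test borrows spread across genes. A fold against a group with 0 counts in every library was computed against a floor of 3 counts over the group; floors and counting intervals cover counting error only. Chromosomes, X-linked genes as a class and gene lists were tested with camera (limma 3.58.1, preset inter-gene correlation 0.01, log-CPM with a prior count of 2), which compares a set with all other genes. Chromosomes and lists were adjusted by Benjamini-Hochberg within a comparison. Camera with an estimated correlation was an alternative. So was fry, whose p tests whether a set's genes move on balance one way, without comparing the set with other genes. Genes within 1 and 5 Mb of Xist were compared with other X-linked genes by Fisher's exact test, two-sided.

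The 28 gene lists covered X inactivation (genes around Xist, genes that escape, genes that are inactivated, Xist RNA partners), chromatin (polycomb, chromosome architecture, DNA methylation, imprinted genes), endoderm (primitive, visceral, parietal), other cell types (pluripotency, trophoblast, fibroblast, germline, epithelial, epithelial-mesenchymal transition), signalling (FGF and MAPK, TGF-beta and BMP, WNT targets) and cell state (cell cycle, p53 targets, interferon, early stress genes, integrated stress and unfolded protein response, cholesterol, lysosome and endocytosis, glycolysis and hypoxia). The groups, tests, lists and the rule for named genes were chosen before the data were examined. The rule took, per comparison, the 10 higher and 10 lower genes with the largest change among changed genes. Each had a mean of at least 2 CPM, and all libraries of one group lay above all of the other. The rule left out symbols made of Gm plus digits, symbols ending in Rik or -ps plus digits, and clone names beginning AC, AL, BC or LOC. It added Xist, all tested genes of the list around Xist, and up to 4 members per list with the lowest p. For WT_clone against WT_EV it took 5 higher and 5 lower genes. The text names examples from the rule's genes, and some of the genes around Xist are not reported here. Mark1, Pnkd, S100g, Rpl7a, Col4a1, Col4a2, Hist3h2a, Fgf13, 4933402E13Rik and Tcf24, and the library counts given for individual marker genes, were chosen after their values were seen.

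Because the counts varied with GC content, a second fit was added after the data were seen. In each library the log2 CPM, with 0.5 added to the count, minus the mean over libraries was regressed robustly (rlm of MASS 7.3.60.0.1) on splines of GC content (6 degrees of freedom) and length (4 degrees of freedom), leaving out the 20% of genes with the lowest mean, and the fitted trend was used as an offset. It covered 15311 of the genes tested (99.87%). Medians by GC content used genes of at least 512 nt, and chromosome medians per library used genes at log2 CPM of at least 3. Other alternatives were DESeq2 1.42.0, RLE scaling, TMM from autosomal genes, no filter on low counts, at least 1 CPM in 3 libraries, only the groups compared, a replicate block, other controls, fewer gene classes, and leaving out each library. Simulated negative binomial counts with the dispersions of these libraries were used to test the code: at a true log2 change of 2 it recovered 69.7% of changed genes for paternal against WT_EV, 59.1% for homozygous against WT_EV and 43.9% between the deletions. At a change of 1 these shares were 5.97%, 4.48% and 2.99%. Each size of change was given to 66 or 67 genes above 2 CPM, among 14057 to 14139 tested. Against WT_EV most genes were called in the real data, which makes the adjustment less strict. The shares therefore do not give the power of those comparisons. False calls numbered 8, 4 and 2, or 13.8%, 8.70% and 5.88% of all calls. With a simulated GC trend, 63.5% of unchanged genes were called without the offset and 0.0606% with it. The simulated trend came from the same spline fit, so its removal was built in. Figures used Python 3.11.15 with matplotlib 3.10.9. The ChIP-seq and 4C data that the study mentions were not used here.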

Results

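RNA-seq read counts per gene were compared in mouse XEN cells, a stem cell line of the extra-embryonic endoderm in which the paternal X chromosome is the inactive one by imprint. The labels give 4 groups: wild type WT_EV (n = 3), a deletion upstream of Xist on the paternal X, DXp (n = 2), the homozygous deletion, DXp_DXm (n = 2), and wild-type clones, WT_clone (n = 2). Total counts in WT_EV replicates 1 to 3 were 15282608, 19833044 and 14352719. They were 24586135 and 29335803 in DXp replicates 1 and 2, and 25589912 and 27334893 in DXp_DXm replicates 1 and 2. The 2 WT_clone libraries had 7641676 and 5825838 counts in the part of their table that was held, where the other 7 libraries had 2298180 to 6687693. Between 18909 and 20374 genes had a count in each of the 7 libraries.

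The first question was whether a deletion upstream of Xist changes the level of Xist itself, the non-coding RNA that coats and silences the X chromosome. Xist (ENSMUSG00000086503) lies on the minus strand of chromosome X at 103460366 to 103483254 in GRCm38. Its level was 1068 ± 448 CPM in WT_EV (SD, n = 3), 16381 ± 1321 CPM in DXp (n = 2) and 7206 ± 2469 CPM in DXp_DXm (n = 2). Xist was 15.3-fold higher in DXp than in WT_EV, a log2 change of 3.94 (SE 0.38, interval 2.88 to 4.99, adjusted p 1.26e-05). It was 6.75-fold higher in DXp_DXm, a log2 change of 2.75 (SE 0.37, interval 1.74 to 3.77, adjusted p 1.20e-04). Between the deletions the log2 change was -1.18 (SE 0.40, interval -2.30 to -0.07, unadjusted edgeR p 0.0147). It did not pass in edgeR when adjusted over all genes (adjusted p 0.143). It passed in DESeq2, at -1.29 (adjusted p 0.0358), and in edgeR without the filter on low counts, at -1.18 (adjusted p 0.00737). With offsets for GC content and length, Xist rose by 1.64 in DXp (interval 0.89 to 2.39, adjusted p 0.00122) and by 1.02 in DXp_DXm (interval 0.27 to 1.77, adjusted p 0.0155), log2 scale. In the 9-library fit of shared genes with offsets, Xist against WT_EV rose by 1.52 in DXp (adjusted p 0.00290). There it did not pass in DXp_DXm, at 0.78 (adjusted p 0.0714).

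The WT_clone libraries held more Xist than WT_EV. Xist took 0.778 ± 0.326% of the counts of shared genes in WT_EV (SD, n = 3), 1.72 ± 0.537% in WT_clone (n = 2), 2.80 ± 0.971% in DXp_DXm (n = 2) and 5.91 ± 0.104% in DXp (n = 2). WT_clone exceeded WT_EV by a log2 change of 1.56 (SE 0.37, adjusted p 0.0112), or 0.83 with offsets, which did not pass (adjusted p 0.0708). Against WT_clone, Xist was 3.99-fold higher in DXp (adjusted p 0.00408) and did not pass in DXp_DXm, at a log2 change of 0.79 (SE 0.42, adjusted p 0.189). With offsets neither comparison with WT_clone passed, at 0.69 for DXp (interval -0.17 to 1.56, adjusted p 0.193) and -0.050 for DXp_DXm (interval -0.91 to 0.81, adjusted p 0.967). The labels do not give the deleted segment, so the genotypes could not be checked in the counts.

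**Figure D1:**
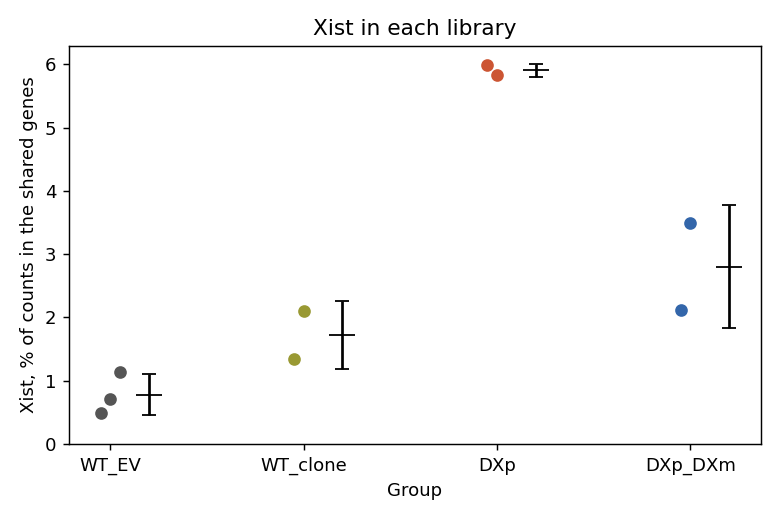
Xist counts as a percentage of the counts of shared genes in each of the 9 libraries, with the mean and SD of each group. The DXp libraries lie at 5.83 and 5.98%, and the WT_EV libraries between 0.492 and 1.13%.

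The comparison of DXp with WT_EV asked which genes differ when the paternal X carries the deletion. The WT_EV libraries also held RNAs without a poly(A) tail that the deletion libraries nearly lacked, such as Rn7sk (157188 to 255029 counts against 2 to 7). A difference in RNA selection, weighed below, therefore cannot be told apart from the genotype by this comparison alone. Copine 8 (Cpne8), a calcium-dependent membrane-binding protein, had 69.4 ± 14.5 CPM in DXp (n = 2) and no count in WT_EV (n = 3), at least 1346-fold higher (adjusted p 4.58e-06). The lipid enzyme gene Lpcat2 was at least 320-fold higher (16.5 ± 12.1 CPM), the lymphatic growth factor gene Vegfc at least 186-fold (9.60 ± 3.26 CPM) and the monoamine transporter gene Slc18a2 at least 132-fold (6.83 ± 1.86 CPM). The zinc-finger genes Zc3h12c and Zfp105 were at least 126-fold and 125-fold higher. Car13, a carbonic anhydrase gene, had 21.8 ± 0.203 CPM in DXp against 1 count over the WT_EV libraries, and Cpe, which encodes a prohormone-processing enzyme, 42.8 ± 37.1 CPM against 2 counts. Hhip, an inhibitor of hedgehog signalling, rose from 0.116 ± 0.101 to 102 ± 20.8 CPM, a log2 change of 9.67 (SE 0.67, adjusted p 4.52e-06). In all, 11079 of 15331 genes changed (72.3%), 4930 higher and 6149 lower, of which 4529 and 5899 by at least 2-fold. With GC and length offsets 7588 genes changed (49.5%), 3610 higher and 3978 lower; 5346 of the genes had changed in the same direction without offsets and 631 in the opposite direction.

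The lower genes in DXp were led by RNAs that lack a poly(A) tail. Rn7sk, the RNA that holds the elongation factor P-TEFb inactive, fell from 10664 ± 3251 CPM in WT_EV (n = 3) to 0.154 CPM in DXp (n = 2), a log2 change of -16.03 (SE 0.66, adjusted p 3.24e-06). The histone gene Hist1h3e had 587 ± 446 CPM in WT_EV and no count in DXp, at least 8895-fold lower, and Hist2h3b was at least 6526-fold lower. Hist1h4a had 810 ± 329 CPM in WT_EV and 1 count over the DXp libraries. The Cajal-body guide RNAs Scarna13 and Scarna2 were at least 2076-fold and 1871-fold lower. Of 63 replication-dependent histone genes, 59 fell and 1, Hist3h2a, rose (median log2 change -9.36 with genes at 0 counts set to their bound). Hist3h2a did not pass without WT_EV replicate 1 or 2 or DXp replicate 2 (adjusted p 0.125, 0.121 and 0.237). Of 141 miRNA genes, 117 fell and 12 rose (median -4.14 with bounds). Of 237 small nuclear, nucleolar, Cajal-body and miscellaneous RNA genes, 143 fell and 26 rose (median -2.82 with bounds). Among the other 11875 protein-coding genes, 4214 rose and 4750 fell. Histone genes took 0.985 to 2.46% of all counts in WT_EV and 0.00129 to 0.00685% in the 4 deletion libraries. Histone and 7SK genes have near-identical copies, so counts of single members are uncertain.

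The change in DXp also followed the GC content of the transcript. The median log2 change was 2.25 for 1856 genes under 42% GC, 1.18 for 3758 genes at 42 to 48%, -0.81 for 3667 genes at 48 to 54% and -3.42 for 2837 genes over 54%. GC content and length together explained 54.3% of the variance of log2 changes in DXp and 54.1% in DXp_DXm, and 10.4% between the deletions. In DXp_DXm the medians of those GC classes were 1.81, 1.09, -0.50 and -3.05. Values with offsets are therefore given beside most of the list genes named.

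**Figure D2:**
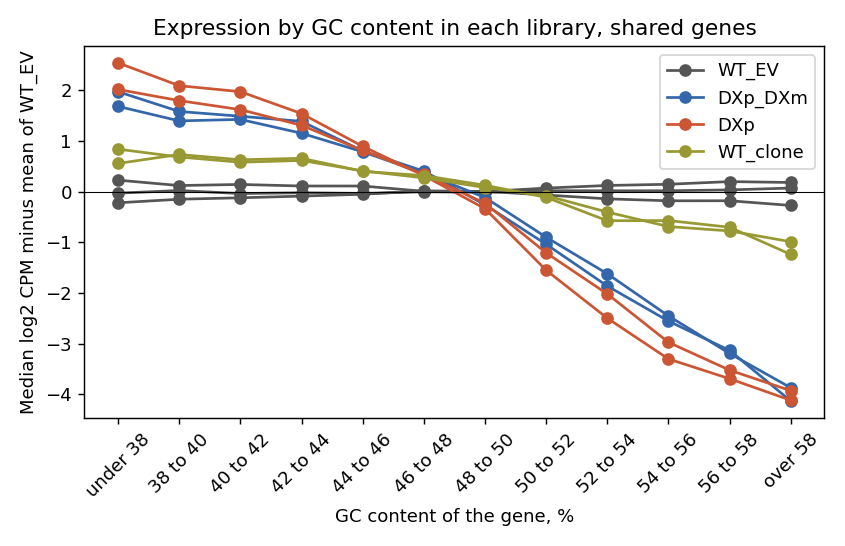
Median log2 CPM of genes in each of 12 bins of transcript GC content, minus the mean of the WT_EV libraries, for each of the 9 libraries. The 4 deletion libraries slope from above 0 at low GC content to below 0 at high GC content, and the WT_clone libraries slope the same way by less, from 0.84 and 0.56 in the lowest bin to -0.99 and -1.24 in the highest.

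Genes of chromosome architecture rose as a group in DXp. Of 17 tested, 13 rose, 1 fell and 3 did not pass, with a median log2 change of 2.18 (camera adjusted p 0.00162). Adjusted over the list alone, 14 passed. The call did not hold with an estimated correlation (adjusted p 0.895) or with offsets, where 7 rose and 3 fell (adjusted p 0.396). Smc4, a condensin subunit, rose from 194 ± 37.5 to 2334 ± 842 CPM, log2 3.59 (SE 0.32, adjusted p 8.44e-06), or 1.43 with offsets. Top2b, a topoisomerase, rose by 3.34 (SE 0.25, adjusted p 4.72e-06), or 1.18 with offsets.

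Other chromatin groups in DXp moved both ways. Of 27 polycomb genes, 13 rose, 11 fell and 3 did not pass, and 25 passed when adjusted over the list alone. Suz12, a core subunit of the complex that methylates histone H3, rose from 86.6 ± 10.8 to 1446 ± 201 CPM, log2 4.06 (SE 0.27, adjusted p 4.46e-06), or 2.15 with offsets. Of 19 genes whose proteins bind Xist RNA or act with it, 11 rose, 7 fell and 1 did not pass, and 18 passed when adjusted over the list alone. With offsets 3 of them rose and 6 fell. Of 17 DNA methylation genes, 4 rose, 8 fell and 5 did not pass, and 12 passed when adjusted over the list alone. Of 21 imprinted genes, 9 rose, 5 fell and 7 did not pass, and 14 passed when adjusted over the list alone. The imprinted zinc-finger gene Plagl1 rose from 13.4 ± 2.20 to 237 ± 101 CPM, log2 4.14 (SE 0.34, adjusted p 6.02e-06), or 3.16 with offsets. Of 27 X-linked genes subject to inactivation, 15 rose, 8 fell and 4 did not pass, and of 14 genes that escape it, 6 rose, 1 fell and 7 did not pass. Adjusted over the list alone, 23 and 7 of these passed. With offsets 8 of the inactivated genes rose and 9 fell, and 3 of the escaping genes rose and 5 fell. Lamp2 rose by 4.16 (SE 0.29, adjusted p 4.46e-06), or 1.64 with offsets. Atrx rose by 2.88 (SE 0.22, adjusted p 5.03e-06), and with offsets its change of 0.25 did not pass (adjusted p 0.278). None of these lists passed with camera in DXp.

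Genes of endoderm identity in DXp fell more often than they rose without offsets. Of 20 primitive endoderm genes, 3 rose, 7 fell and 10 did not pass. Of 15 visceral endoderm genes, 1 rose, 8 fell and 6 did not pass. Of 18 parietal endoderm genes, 3 rose, 7 fell and 8 did not pass. Adjusted over the list alone, 10 primitive, 9 visceral and 10 parietal genes passed. With offsets the balance of the endoderm lists flipped or was lost: 9 of the primitive endoderm genes rose, 4 visceral genes rose and 4 fell, and 6 parietal genes rose and 4 fell. The endoderm factor gene Gata4 fell from 706 ± 69.6 to 132 ± 36.6 CPM, log2 -2.42 (SE 0.27, adjusted p 3.17e-05), but with offsets rose by 0.90 (adjusted p 0.0128). Nid1, a basement membrane linker, rose from 511 ± 72.2 to 4508 ± 857 CPM, log2 3.14 (SE 0.25, adjusted p 5.49e-06), or 3.56 with offsets. Of 25 cell cycle genes, 8 rose, 12 fell and 5 did not pass, and 21 passed when adjusted over the list alone. With offsets 4 rose and 14 fell, with a median of -0.91, and camera did not call the list (adjusted p 0.214). The helicase subunit genes Mcm5 and Mcm2 fell, with log2 changes of -4.25 (SE 0.31) and -3.58 (SE 0.27), both at adjusted p 4.58e-06, and of -2.91 and -2.62 with offsets. The immediate early gene Fos rose from 4.56 ± 5.42 to 176 ± 7.54 CPM, log2 5.29 (SE 0.86, adjusted p 6.80e-04), or 6.79 with offsets. Camera called 1 of the 28 lists in DXp with its preset correlation, the architecture list, and none with an estimated correlation, where the lowest adjusted p was 0.895. Fry called 20.

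The comparison of DXp_DXm with WT_EV asked which genes differ when both X chromosomes carry the deletion. As for DXp, a difference in RNA selection cannot be told apart from the genotype by this comparison alone. Cpne8 was again absent from WT_EV (n = 3) and had 26.1 ± 12.5 CPM in DXp_DXm (n = 2), at least 507-fold higher (adjusted p 9.94e-06). Zfp105 was at least 179-fold higher (9.24 ± 5.29 CPM), Lpcat2 at least 170-fold (8.77 ± 2.49 CPM) and Vegfc at least 85.8-fold (4.43 ± 1.48 CPM). Esrp1, an epithelial splicing regulator, rose from 0.0962 ± 0.0868 to 45.6 ± 25.3 CPM, log2 8.73 (SE 0.75, adjusted p 1.29e-05). The noradrenaline transporter gene Slc6a2 rose by 7.94 (SE 0.85, adjusted p 6.25e-05). B3gnt3, a glycosyltransferase gene, had 32.0 ± 19.2 CPM in DXp_DXm against 1 count over WT_EV, and the neurofilament gene Nefl 17.6 ± 17.7 CPM against 3 counts. In all, 10243 of 15331 genes changed (66.8%), 4730 higher and 5513 lower, of which 4189 and 5289 by at least 2-fold. With offsets 6216 changed (40.5%), 2918 higher and 3298 lower; 4413 had changed in the same direction without offsets and 441 in the opposite direction.

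The same RNA classes were low in DXp_DXm. Rn7sk fell by 15.80 on the log2 scale (SE 0.65, adjusted p 3.01e-06). The histone genes Hist1h3e, Hist2h2ac and Hist1h4h had no count in DXp_DXm and were at least 9700-fold, 8442-fold and 8363-fold lower. Of 63 histone genes, 60 fell and none rose (median -9.18 with bounds). Of 141 miRNA genes, 115 fell and 10 rose (median -4.33 with bounds). Of the 237 other small RNA genes, 134 fell and 16 rose (median -2.66 with bounds). Of the other 11875 protein-coding genes, 4080 rose and 4209 fell.

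Among chromatin genes in DXp_DXm, 15 of 17 architecture genes rose, 1 fell and 1 did not pass, with a median of 1.98 (camera adjusted p 0.00102). Adjusted over the list alone 16 passed, and the call did not hold with an estimated correlation (adjusted p 0.921) or with offsets, where 6 rose and 1 fell (adjusted p 0.585). Pds5b, a cohesin regulator, rose from 46.1 ± 7.40 to 308 ± 102 CPM, log2 2.74 (SE 0.27, adjusted p 2.42e-05), or 0.92 with offsets. Suz12 rose by 3.57 (SE 0.27, adjusted p 8.34e-06), or 1.95 with offsets. Lamp2 rose by 2.92 (SE 0.28, adjusted p 1.91e-05), or 1.03 with offsets. The imprinted gene Peg10 rose from 112 ± 14.8 to 983 ± 473 CPM, log2 3.13 (SE 0.35, adjusted p 4.65e-05), or 2.42 with offsets. Plagl1 rose by 2.37 (SE 0.32, adjusted p 1.40e-04). Of the X-linked genes, 15 of 27 subject to inactivation rose and 6 fell, and 8 of 14 that escape rose and 1 fell (camera adjusted p 0.158 for both lists). With offsets the excess of higher genes was lost, with 6 higher and 7 lower in the inactivated list and 2 higher and 3 lower in the escaping list.

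Endoderm and signalling genes in DXp_DXm again moved both ways. Of 20 primitive, 15 visceral and 18 parietal endoderm genes, 4, 2 and 3 rose and 8, 7 and 7 fell. Adjusted over the list alone, 12, 9 and 10 passed. With offsets 8, 4 and 6 rose and 1, 4 and 3 fell. Gata4 fell by 2.79 (SE 0.28, adjusted p 2.45e-05), and with offsets its change of 0.28 did not pass (adjusted p 0.382). Sox7, an endoderm factor gene, rose from 87.8 ± 9.44 to 292 ± 158 CPM, log2 1.73 (SE 0.33, adjusted p 0.00104), or 2.31 with offsets. Mcm2 fell by 3.20 (SE 0.26, adjusted p 1.03e-05), and with offsets fell by 2.53. Of 16 FGF and MAPK genes, 2 rose, 7 fell and 7 did not pass. Of 18 genes of the integrated stress and unfolded protein response, 4 rose, 9 fell and 5 did not pass. Of 23 glycolysis and hypoxia genes, 7 rose, 12 fell and 4 did not pass. Of these, 8, 13 and 19 passed when adjusted over the list alone. With offsets 2 FGF and MAPK genes rose and 4 fell, but 6 stress response genes rose and 4 fell, and 8 glycolysis and hypoxia genes rose and 4 fell. The architecture list was the 1 list of 28 that camera called, none was called with an estimated correlation (lowest adjusted p 0.894), and fry called 14.

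The comparison of DXp_DXm with DXp asked which genes differ when the maternal copy is deleted as well. A difference between lines, named D3 and D1 in the titles, would give such values too. Kcnk1, a potassium channel gene, had 82.2 ± 16.8 CPM in DXp_DXm and 0.345 ± 0.379 CPM in DXp (n = 2 each), log2 7.98 (SE 0.66, adjusted p 0.00432). Esrp1 had 45.6 ± 25.3 against 0.218 ± 0.198 CPM, log2 7.76 (SE 0.83, adjusted p 0.0137). Dut, which removes dUTP, rose by 2.38 (SE 0.29, adjusted p 0.0311), Cops9, of the COP9 signalosome, by 2.43 (SE 0.32, adjusted p 0.0314), and the chaperone gene Hsph1 by 1.56 (SE 0.25, adjusted p 0.0406). The DNA glycosylase gene Neil3 fell from 102 ± 51.9 to 1.05 ± 0.901 CPM, log2 -6.59 (SE 0.70, adjusted p 0.0137). The transcription factor gene Fosb fell by 5.14 (SE 0.80, adjusted p 0.0388). Hhip and the kinase gene Stk39 fell, with log2 changes of -4.13 (SE 0.57) and -3.68 (SE 0.53), both at adjusted p 0.0314. The retinol carrier gene Rbp4 and the selenium carrier gene Selenop fell as well, at -3.17 (SE 0.46) and -3.09 (SE 0.42) with the same adjusted p. Armcx3 had 3 counts in DXp_DXm and 1135 in DXp, and the phospholipase gene Pla2g4a 2 and 326 counts. The repressor gene Zeb1 fell from 130 ± 14.3 to 26.0 ± 8.24 CPM, log2 -2.32 (SE 0.30, adjusted p 0.0314), and the chaperone gene Dnajb9 fell by 1.69 (SE 0.26, adjusted p 0.0351).

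Between the deletions 68 genes changed, 43 higher and 25 lower in DXp_DXm, all by at least 2-fold, and 3196 had an unadjusted p under 0.05. DESeq2 called 1167 genes, and edgeR without the filter on low counts 1436. The 7-library fit takes its spread from WT_EV as well. Fitted on the 2 deletion groups alone, edgeR called 10 genes, 8 of them among the 68 and in the same direction. Of the 24 changed genes of the naming rule, 6 passed there. With offsets 51 changed, 26 higher and 25 lower, 42 of them as without offsets. Kcnk1, Esrp1, Dut, Cops9, Nudc, Hsph1, Neil3, Fosb, Hhip, Stk39, Armcx3, Zeb1, Pcdhb22 and Dnajb9 passed with offsets too. Genes that did not pass with offsets included the glycolysis genes Pgam1, at 2.30 without offsets (SE 0.38, adjusted p 0.0424, with offsets 0.0763), and Eno1, at 1.93 (SE 0.32, adjusted p 0.0423, with offsets 0.0719). Arhgap8, Car4, Ndufa9, Nptxr and Pcdhb19 did not pass with offsets either. The number changed depended on single libraries. It was 4 without WT_EV replicate 1, 21 without replicate 2 and 480 without replicate 3. It was 10 without DXp_DXm replicate 1 and 144 without replicate 2, and 3 without DXp replicate 1 and 2 without replicate 2. Kcnk1 passed whichever of the 7 libraries was left out. Neil3 passed in all but the fit without DXp replicate 1 (adjusted p 0.0501), and Esrp1 in all but those without DXp replicate 1 or 2 (adjusted p 0.0573 and 0.0873). Each other changed gene named between the deletions lost its call in at least 2 of the 7 fits, with its direction kept. Of the 24 genes of the naming rule that changed, 3, 13 and 24 passed without WT_EV replicates 1, 2 and 3. Without DXp_DXm replicates 1 and 2, 7 and 18 passed, and without DXp replicates 1 and 2, 1 and 2 passed. Fos, from 176 to 3.02 CPM (log2 -5.86, adjusted p 0.0590), and Peg10 (log2 2.03, adjusted p 0.0590) did not pass.

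**Figure D3:**
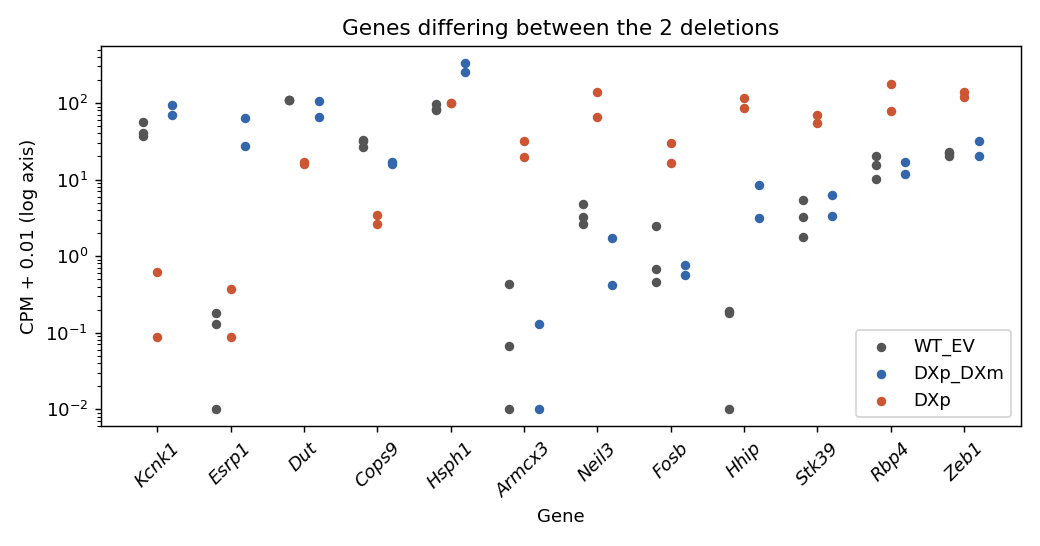
CPM plus 0.01, on a log axis, of 12 genes that changed between DXp_DXm and DXp, for each of the 7 libraries. Kcnk1 lies at 70.4 and 94.0 CPM in the DXp_DXm libraries and below 1 CPM in both DXp libraries.

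As a group, cell cycle genes were higher in DXp_DXm than in DXp. Of 25 tested none passed singly in edgeR, 14 had an unadjusted p under 0.05 and 5 passed when adjusted over the list alone, with a median log2 change of 0.60 (camera adjusted p 0.0237). The call did not hold with an estimated correlation (adjusted p 0.835). With offsets the list passed with the preset correlation (adjusted p 0.0149) but not with an estimated one (adjusted p 0.953). Mcm7 and Mcm6 had log2 changes of 1.45 and 1.20, with adjusted p 0.0581 and 0.0605. Of 14 early stress genes, Hsph1 rose, Fosb fell and 12 did not pass (3 passed when adjusted over the list alone), with a median of -1.50 (camera adjusted p 0.0418, with an estimated correlation 0.835). Of 7 WNT targets none passed singly in edgeR, 4 had an unadjusted p under 0.05 and 2 passed when adjusted over the list alone, with a median of -0.81 (camera adjusted p 0.0418, with an estimated correlation 0.835); Axin2 and Tnfrsf19 had log2 changes of -4.55 and -4.89, with adjusted p 0.0883 and 0.0590. Of 12 genes of epithelial-mesenchymal transition Zeb1 fell, and of 15 epithelial genes Esrp1 rose; 4 and 5 passed when adjusted over the list alone. With offsets camera called 4 of 28 lists, the additional one being FGF and MAPK (adjusted p 0.0351, with an estimated correlation 0.953). With an estimated correlation none of the 28 was called (lowest adjusted p 0.835, with offsets 0.953), nor by fry. Without DXp_DXm replicate 1 or DXp replicate 1 camera called 6 lists, and without DXp replicate 2 it called 0.

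Whether the silencing of the X as a whole differed was asked of all X-linked genes tested. In DXp 267 of 510 rose and 118 fell, with a median log2 change of 1.10 against -0.41 for 14795 autosomal genes, of which 4651 rose and 6027 fell (camera p 4.96e-06, with an estimated correlation p 0.0107). In DXp_DXm 255 rose and 90 fell, with a median of 0.97 against -0.20 (camera p 3.22e-06, with an estimated correlation p 0.01004). X-linked transcripts had a median GC content of 45.4% and autosomal ones of 48.8%. With offsets the medians were 0.29 against -0.11 in DXp (camera p 0.0409) and 0.29 against -0.06 in DXp_DXm (camera p 0.0468). These p-values are for the X alone. Adjusted over all chromosomes, the X did not pass with offsets (camera adjusted p 0.409 in DXp and 0.452 in DXp_DXm). Without offsets it then passed with the preset correlation but not with an estimated one (adjusted p 0.137 and 0.201). Between the deletions S100g and 4933402E13Rik rose, by 2.22 (adjusted p 0.0424) and 6.75 (adjusted p 0.0137), and Armcx3 and Fgf13 fell. The medians were -0.11 for X-linked and 0.03 for autosomal genes (camera p 0.0866). X-linked genes were also higher in WT_clone than in WT_EV, with 102 of 532 higher and 34 lower and medians of 0.33 and -0.03 (camera p 0.00271). That call did not hold with an estimated correlation (p 0.0662), while the one with offsets, medians 0.19 and -0.08, did (camera p 0.0150, with an estimated correlation p 0.0369). Against WT_clone without offsets, X-linked genes had medians of 0.46 against -0.17 in DXp (camera p 0.00844, with an estimated correlation p 0.0948) and 0.23 against -0.06 in DXp_DXm (camera p 0.0467, with an estimated correlation p 0.181). With offsets they did not pass against WT_clone in DXp (camera p 0.229) or DXp_DXm (camera p 0.907). Alleles were not told apart, so a change of either parental copy would give these values.

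Genes beside Xist were examined because the deletion lies there. Chic1, next to Xist, rose by 2.93 in DXp (SE 0.32, adjusted p 2.67e-05) and by 2.05 in DXp_DXm (SE 0.32, adjusted p 3.09e-04). With offsets its changes of 0.44 and 0.13 did not pass (adjusted p 0.198 and 0.710). Zdhhc15 rose by 2.21 in DXp (SE 0.27) and 1.42 in DXp_DXm (SE 0.27), and did not pass with offsets. Against WT_clone with offsets both passed in DXp, Chic1 at 1.14 (adjusted p 0.0441) and Zdhhc15 at 1.28 (adjusted p 0.0277), and neither in DXp_DXm (adjusted p 0.218 and 0.249). Jpx and Ftx, non-coding genes that promote Xist transcription, did not pass without offsets, at 0.07 and -0.38 in DXp and 0.49 and 0.44 in DXp_DXm. With offsets Jpx fell by 1.79 in DXp (adjusted p 0.00314) and fell by 1.04 in DXp_DXm (adjusted p 0.0381). Ftx changed by -1.92 (adjusted p 0.00120) and -0.85 (adjusted p 0.0475). The same offsets gave changes of -1.63 for Jpx (adjusted p 0.0158) and -1.55 for Ftx (adjusted p 0.0195) in WT_clone against WT_EV. Rlim, whose protein activates Xist, rose by 1.13 in DXp (SE 0.37, adjusted p 0.0194), but with offsets fell by 1.09 (adjusted p 0.0245). With offsets its change was -1.10 in WT_clone against WT_EV as well (adjusted p 0.0461), and 0.02 in DXp against WT_clone (adjusted p 0.993). The call without offsets was lost without WT_EV replicate 1 (adjusted p 0.0623), WT_EV replicate 2 (adjusted p 0.0687) or DXp replicate 1 (adjusted p 0.0739). Hdac8 fell by 1.57 in DXp (SE 0.45, adjusted p 0.00972), and did not pass without DXp replicate 1 (adjusted p 0.0786). With offsets Hdac8 changed by -3.19 in DXp (adjusted p 7.36e-04) and by -2.04 in DXp_DXm (adjusted p 0.00622), where it did not pass without them (adjusted p 0.230). Its change in WT_clone against WT_EV with offsets, -1.06, did not pass (adjusted p 0.123). Against WT_clone with offsets it changed by -2.17 in DXp (adjusted p 0.0208) and did not pass in DXp_DXm (adjusted p 0.219). Tsix did not pass in DXp (adjusted p 0.660) or DXp_DXm (adjusted p 0.539), and its counts are uncertain because it overlaps Xist on the other strand.

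Of the 13 tested genes of the list around Xist, 6 rose and 2 fell in DXp, and 6 rose and 1 fell in DXp_DXm. When adjusted over the list alone, 8 and 7 passed. The annotation puts one of the 13, Ppnr, on chromosome 19, so it does not lie around Xist. Ppnr fell, with log2 changes of -4.43 in DXp (adjusted p 5.15e-04) and -3.62 in DXp_DXm (adjusted p 0.00150), and was the 1 list gene that fell in DXp_DXm. With offsets 2 list genes were higher and 5 lower in each deletion, the lower ones being Hdac8, Jpx, Ftx and Rlim on the X and Ppnr. Within 1 Mb of Xist, 8 of 14 genes changed in DXp against 376 of 495 other X-linked genes (Fisher's exact p 0.119), and 8 of 14 in DXp_DXm against 336 of 495 (exact p 0.397). In each case 5 rose and 3 fell, but with offsets 2 rose and 5 fell in DXp and 2 rose and 6 fell in DXp_DXm. Within 5 Mb the shares were 44 of 65 against 340 of 444 in DXp (exact p 0.125) and 36 of 65 against 308 of 444 in DXp_DXm (exact p 0.0327). With offsets the difference in DXp_DXm turned round, at 32 of 65 against 170 of 444, and did not pass (exact p 0.104). Between the deletions edgeR called none of the 14 genes, and 2 had an unadjusted p under 0.05.

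Whether whole chromosomes moved was asked with each chromosome's genes as a class. Against WT_EV camera called 7 chromosomes in DXp and 6 in DXp_DXm, none of them with an estimated correlation (lowest adjusted p 0.137 and 0.201). Chromosome 7 had a median of -1.73 in DXp, where 220 of 1125 genes rose and 615 fell (camera adjusted p 0.00286, with an estimated correlation 0.280), and of -1.26 in DXp_DXm (camera adjusted p 0.00282, with an estimated correlation 0.274). Chromosome 1 had medians of 0.39 in DXp (camera adjusted p 0.0489, with an estimated correlation 0.322) and 0.70 in DXp_DXm (camera adjusted p 0.00282, with an estimated correlation 0.274). With offsets neither chromosome passed, at adjusted p 0.728 and 0.535 for chromosome 7 and 0.822 and 0.535 for chromosome 1. On chromosome 18, 198 of 400 genes rose in DXp and 73 fell, with a median log2 change of 0.96 (camera adjusted p 4.96e-05). The call did not hold with an estimated correlation (adjusted p 0.137). With offsets 168 rose and 50 fell (median 0.73, camera adjusted p 5.84e-04, with an estimated correlation 0.0346). In DXp_DXm 160 rose and 89 fell (median 0.41, camera adjusted p 0.0348, with an estimated correlation 0.274), and with offsets 90 rose and 68 fell (median 0.02, camera adjusted p 0.765). Between the deletions the chromosome 18 median was -0.63 (camera adjusted p 3.97e-13, with an estimated correlation 0.0446), and all 8 genes that passed, among them Zeb1, Pcdhb19 and Pcdhb22, were lower in DXp_DXm. Pcdhb22, a protocadherin gene, fell by 2.61 (SE 0.40, adjusted p 0.0387). With offsets the median was -0.65 (camera adjusted p 5.60e-13, with an estimated correlation 0.00340). On chromosome 1, 10 of 956 genes rose in DXp_DXm over DXp and 2, Pla2g4a and Tcf24, fell (median 0.22, camera adjusted p 0.0771). With offsets its median was 0.31 (camera adjusted p 3.49e-04, with an estimated correlation 0.00545). Camera also called chromosome 12 (median -0.33, adjusted p 8.54e-04) and chromosome 19 (median 0.45, adjusted p 0.00131) between the deletions. Neither held with an estimated correlation (adjusted p 0.772 and 0.793), and on chromosome 12 DXp_DXm replicate 1 lay at -0.25 and replicate 2 at 0.31, beside 0.44 and 0.43 in DXp. On chromosome 19 the WT_EV libraries alone lay at 0.06, 0.48 and -0.51, the DXp_DXm libraries at 0.28 and 0.15 and the DXp libraries at -0.40 and -0.15.

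**Figure D4:**
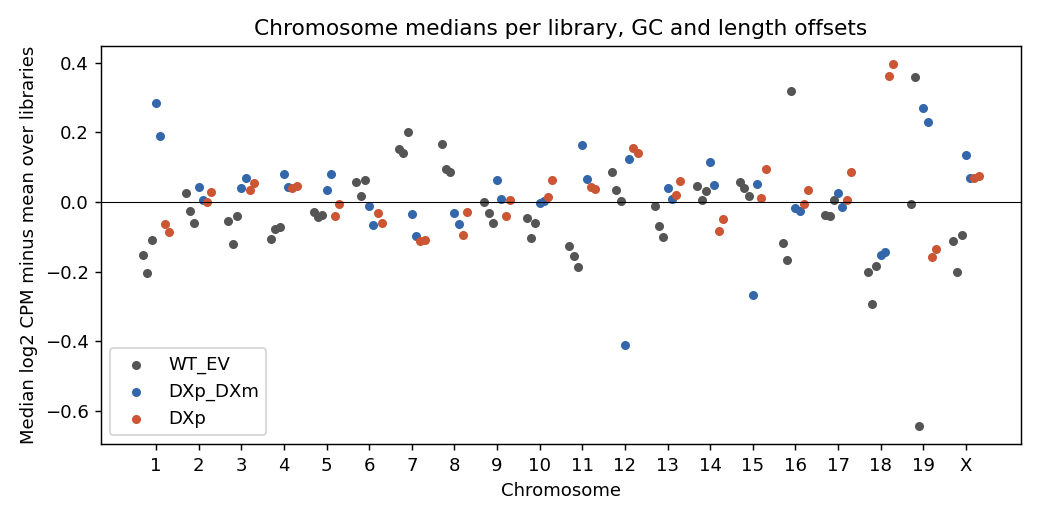
Median log2 expression of the genes of each chromosome in the 7 libraries with GC and length offsets, minus the mean over libraries. On chromosome 18 the DXp libraries lie at 0.36 and 0.40, and the other libraries between -0.29 and -0.14.

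Whether both deletions changed the same genes was asked with the overlap of their changes against WT_EV. Both held 4195 higher genes, where 1521 would be shared by independent draws, and 5109 lower genes, where 2211 would. Across all genes tested, which are not independent replicates, the log2 changes had a Pearson correlation of 0.926 and a covariance of 7.38. With offsets the 2 deletions shared 2363 higher (687 by independent draws) and 2783 lower genes (856), with a correlation of 0.865 and a covariance of 4.34. Because both comparisons used the same 3 WT_EV libraries, unchanged groups were simulated against shared controls. These gave a mean of 0 shared higher and 0.1 shared lower genes, a correlation of 0.400 and a covariance of 0.117. The simulated counts held no GC trend and no loss of RNAs without a poly(A) tail, which both deletions showed against WT_EV. They therefore cannot show whether the overlap comes from the deletions. With disjoint controls on shared genes, DXp against WT_EV and DXp_DXm against WT_clone held 192 higher (70.6 by independent draws) and 515 lower genes (217), with a correlation of 0.499 and a covariance of 2.50. The reverse assignment gave 383 (132) and 618 (264), with a correlation of 0.483 and a covariance of 2.63. With offsets as well, the overlaps were 44 (12.8) and 89 (28.4), with a correlation of 0.231, and 100 (27.6) and 148 (54.8), with a correlation of 0.232. Disjoint controls do not remove what the deletion libraries share beside the genotype. Against WT_clone without offsets, GC content and length still explained 45.8% of the variance of log2 changes in DXp and 46.5% in DXp_DXm. These overlaps therefore cannot show how much comes from the deletions.

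The comparison of WT_clone with WT_EV has no deletion on either side, and so measures what differs between the wild-type libraries. The plexin domain gene Plxdc2 had no count in WT_EV (n = 3) and 395 counts in WT_clone (n = 2), at least 111-fold higher (adjusted p 0.00312). The antigen-presenting gene Mr1 was at least 17.2-fold higher and the sulfiredoxin gene Srxn1 at least 13.8-fold. The miRNA genes Mir669k and Mir466p were at least 81.4-fold and 64.8-fold lower. All 5 lower genes of the rule were miRNA genes on chromosome 2 between 10475300 and 10506094, so genes of this class are not independent. Of 98 miRNA genes, 91 fell and 2 rose (median -4.89 with bounds), and of 58 other small RNA genes, 27 fell and 1 rose (median -2.47). Against WT_clone 1 miRNA gene of 98 rose and none fell in DXp, by the edgeR test, and none changed in DXp_DXm, where 4 had an unadjusted p under 0.05. Of 2401 other protein-coding genes, 456 rose and 217 fell in WT_clone. In all, 1011 of 3302 shared genes changed (30.6%), 504 higher and 507 lower, or 767 with offsets. The count was 557 without WT_EV replicate 1 and 552 without replicate 2.

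Against WT_clone in place of WT_EV, 1329 of the 3302 shared genes changed in DXp, 502 higher and 827 lower, and 824 in DXp_DXm, 243 higher and 581 lower. With offsets these numbers were 487 and 188. Against both WT_EV and WT_clone with offsets, 375 genes changed the same way in DXp, 152 higher and 223 lower. In DXp_DXm 139 did, 47 higher and 92 lower. Both comparisons of a deletion use its same 2 libraries, which by itself makes their calls alike. With and without offsets against both controls, 240 genes changed the same way in DXp and 97 in DXp_DXm, and 71 of them in both deletions. The 2 deletions were compared with the same controls, which also makes their calls alike.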

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

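The tests of this part were chosen after the result was seen, except the test for an extra copy of chromosome 18, whose bins had not been seen when it was written down.

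Genes of chromosomes 1 and 18 stood out because the deletions differed from each other there, by a direct test of the difference with GC and length offsets. On chromosome 1 the median log2 change of DXp_DXm against DXp was 0.31 (camera adjusted p 3.49e-04, with an estimated correlation 0.00545). The medians of 477 chromosome 1 genes were 0.28 and 0.19 in the DXp_DXm libraries, -0.06 and -0.09 in DXp, and -0.20 to -0.11 in WT_EV. Among the shared genes of chromosome 1, WT_clone replicate 2 lay at 0.17 and replicate 1 at -0.06. On chromosome 18 the median log2 change of DXp_DXm against DXp was -0.65 (camera adjusted p 5.60e-13, with an estimated correlation 0.00340), with 19.3% of its genes higher in DXp_DXm.

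Chromosome 18 genes such as Zeb1, Pcdhb19 and Pcdhb22 were higher in both DXp libraries than in the other 5. The trend with GC content and length as the whole cause was argued against, since the median with offsets was still -0.65. The paternal deletion as the whole cause was argued against too: the DXp_DXm cells carry it as well, and with offsets the higher of their libraries exceeded the WT_EV mean by only 0.0839. Without offsets DXp_DXm did lie above WT_EV, by a median of 0.41 (camera adjusted p 0.0348, with an estimated correlation 0.274), but 0.63 below DXp. A smaller part shared by both deletions, or a maternal deletion that undoes the change, therefore stays open. An extra copy of the whole chromosome in the DXp cells would raise all parts of it. In DXp minus DXp_DXm with offsets, the lowest of 5 bins along it had a median of 0.56, the others 0.57 to 0.75. The bins were not compared with WT_EV. A candidate explanation is a gain of chromosome 18 in the DXp culture, which remains a hypothesis because DNA was not analysed here. Single wild-type libraries also had chromosomes that stood apart with offsets. Chromosome 19 lay at -0.01, 0.36 and -0.64 in WT_EV replicates 1 to 3, and chromosome 16 at 0.32 in replicate 3 against -0.12 and -0.17, so such shifts were not limited to deletion libraries.

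Many genes, among them Cpne8, Suz12, Rn7sk and the histone genes, differed between the deletion libraries and WT_EV. The trend with GC content and length as the whole cause was argued against, since 49.5% of genes tested were still called with offsets in DXp. The deletions as the whole cause were argued against, since 30.6% of shared genes were called between the wild-type groups WT_clone and WT_EV. A difference in RNA selection, with RNAs that lack a poly(A) tail kept in WT_EV and lost elsewhere, may explain part, since miRNA genes were lower in WT_clone than in WT_EV too (median -4.89 with bounds). The miRNA genes with the largest falls lay close together on chromosome 2, so the class does not count as independent genes. How many of the remaining changes belong to the deletions stays open, because the wild-type clones had the GC trend of the deletion libraries only in weaker form.

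Xist was higher in both deletions than in WT_EV, whose libraries also stood apart in their mitochondrial share, 6.01 to 9.33% of counts against 1.41 to 3.79% in the deletion libraries. The mitochondrial ribosomal RNA mt-Rnr2 alone took 4.83 to 6.31% of counts in WT_EV. It had 750492 to 957412 counts there and 19611 to 53595 in the deletion libraries. This share therefore cannot be told apart from a difference in RNA selection. For the paternal deletion the trend with GC content and length as the whole cause was argued against, since Xist was still 1.64 higher on the log2 scale with offsets. Whether the deletions raised Xist or WT_EV had a low level cannot be told apart. Against WT_clone with offsets the change was 0.69 in DXp (interval -0.17 to 1.56) and -0.050 in DXp_DXm (interval -0.91 to 0.81), intervals that hold both 0 and a sizeable rise. The difference between the wild-type groups, the 2 libraries per group and the unknown clone history keep it open.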

How the results depend on the processing

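The GC and length offsets, alone or with another choice, and the restriction to protein-coding and long non-coding genes were chosen after the data were seen; the other alternatives were not. Under the alternatives, 215 values of the main results kept direction and side of the threshold (counts within 1.5 times), 64 counts moved, 5 values were weaker, 8 stronger and 1 reversed. For single named genes 2111 kept both, 227 were weaker, 48 stronger and 31 reversed. Except where fewer genes or libraries explain it, the cause was not tested.

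With DESeq2, RLE scaling, autosomal TMM or the filter of 1 CPM, the counts of changed genes against WT_EV stayed within 1.5 times. RLE and DESeq2 moved the median of all genes in DXp by 0.15 and offsets by 0.25, and offsets moved it in DXp_DXm by 0.11 (log2). Between the deletions 63.2% of changed genes were higher, but 47.8% with RLE, 46.9% with DESeq2 and 51.0% with offsets; RLE and DESeq2 scale all genes of a library alike. Of the 24 changed genes of the naming rule between the deletions, all passed with DESeq2, 17 with offsets and 6 with only the groups compared. Of 126 in DXp, 86 were kept with offsets, 31 lost and 9 reversed, and of 122 in DXp_DXm, 84, 26 and 12.

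Between the deletions, DESeq2 called 1167 genes, no filter on low counts 1436, only the compared groups 10, the block by title number (the number in the sample title, which in DXp disagrees with the replicate number) 1573, both controls merged 0 (edgeR, 267 of 3302 at an unadjusted p under 0.05), the fit with WT_clone 6, offsets with the replicate block 39, and offsets with WT_clone 8. Xist between them was -1.29 with DESeq2 (adjusted p 0.0358), -1.18 without the filter (adjusted p 0.00737) and -1.23 with the block by title number (adjusted p 0.0185). X-linked minus autosomal medians were -0.17 with merged controls (p 0.0282), -0.17 in the fit with WT_clone (p 0.0233, with an estimated correlation 0.137) and -0.21 for protein-coding and long non-coding genes (p 0.0205), the first and last not run with an estimated correlation. Gene lists called were 1 with RLE, 1 with the filter of 1 CPM, 1 with merged controls, 0 with WT_clone, 6 with offsets and block, 0 with offsets and WT_clone, 0 with an estimated correlation and 0 with fry.

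With fewer genes tested, merged controls called 1441 genes in DXp and 946 in DXp_DXm, and WT_clone as control 1329 and 824. Offsets called 6216 in DXp_DXm. Offsets with the replicate block called 6855 and 5400, and offsets with WT_clone 487 and 188. Xist in DXp_DXm was 1.52 with merged controls (adjusted p 0.0711), 0.79 with WT_clone and -0.050 with WT_clone and offsets, and Xist in DXp was 0.69 with the latter. With WT_clone and offsets, X-linked minus autosomal medians were 0.060 in DXp (p 0.229) and 0.014 in DXp_DXm (p 0.907). Gene lists called in DXp and DXp_DXm were 0 and 0 with merged controls, WT_clone, offsets, offsets with WT_clone, or an estimated correlation. They were 2 and 0 with offsets and block, and 20 and 14 with fry. Chromosomes called with offsets were 1 in DXp and 0 in DXp_DXm, from 7 and 6. Within 5 Mb of Xist 36 genes changed in DXp_DXm (exact p 0.0327), and 32 with offsets (exact p 0.104). Disjoint controls, with fewer genes, left overlaps of 192 and 383 higher and 515 and 618 lower genes, and with offsets 44 and 100 higher and 89 and 148 lower.

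Among single genes named in the text, whether or not they had passed, reversals came mostly with offsets. In DXp these were Jpx -1.79, Rlim -1.09, Tsix -0.66, Gata4 0.90 and Col4a1 0.048. In DXp_DXm they were Ftx -0.85, Jpx -1.04, Rlim -1.03, Zdhhc15 -0.14 and Gata4 0.28. With offsets and the replicate block, values in DXp were Jpx -1.50, Rlim -0.65 and Gata4 1.11. In DXp_DXm they were Ftx -0.57, Jpx -0.75, Rlim -0.60, Zdhhc15 -0.088 and Gata4 0.49. With offsets and WT_clone, values in DXp were Atrx -0.39 and Jpx -0.17, and in DXp_DXm Lamp2 -0.014. With WT_clone alone they were Ftx 0.21 in DXp and Tsix 0.017 in DXp_DXm. Tsix in DXp_DXm was 0.16 with the replicate block and 0.43 with the block by title number.

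Leaving out 1 library at a time, where a lone library is assumed to vary like the other groups, gave 9670 to 11384 changed genes in DXp, 8646 to 10507 in DXp_DXm, 2 to 480 between the deletions (with offsets 2 to 66) and 552 to 1057 in WT_clone. Xist ranged from 3.68 to 4.30 in DXp, 2.37 to 3.15 in DXp_DXm and -1.58 to -0.87 between the deletions. X-linked minus autosomal medians ranged from 1.42 to 1.69, 1.10 to 1.31 and -0.22 to -0.038. Gene lists called were 1 in DXp and DXp_DXm and 0 to 6 between the deletions. Jpx in DXp ranged from -0.18 to 0.42 and reversed, at -0.06 without DXp replicate 1, -0.18 without WT_EV replicate 1 and -0.02 without WT_EV replicate 2. Tsix in DXp ranged from -0.15, without DXp replicate 2, to 1.64. In DXp_DXm it ranged from -2.46 to 0.54, at 0.20 without DXp_DXm replicate 1 and 0.54 without WT_EV replicate 3.

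Centred profiles of like replicate number in the deletions correlated at -0.327 and of like title number at 0.327, and with 2 libraries per deletion neither shows a pairing. The replicate block gave 10638 and 9668 changed genes against WT_EV, 92 between the deletions and 847 in WT_clone. Depth and spread limit small changes between the deletions, since a simulated log2 change of 1 was recovered there in 2.99% of genes when few genes changed.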

Other observations

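Tests and genes of this part were chosen after the data were seen, except the gene lists.

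Some genes changed the same way against both wild-type groups, with and without offsets. S100g, an X-linked calcium-binding protein gene, fell in DXp by log2 changes of -4.91 against WT_EV and -5.01 against WT_clone, and of -4.47 and -4.58 with offsets (adjusted p 1.42e-04 and 7.95e-04). In DXp_DXm its changes with offsets were -2.55 and -2.66 (adjusted p 0.00160 and 0.00901). Pnkd, a hydrolase gene on chromosome 1, fell with offsets by changes of -4.34 and -3.50 in DXp and -4.80 and -3.96 in DXp_DXm. Mark1, a microtubule-affinity kinase gene on chromosome 1, rose with offsets by 5.66 and 4.82 in DXp and by 5.85 and 5.02 in DXp_DXm. The ribosomal protein gene Rpl7a fell with offsets by changes of -3.10 and -3.01 in DXp and -3.54 and -3.45 in DXp_DXm, though its processed pseudogenes make its counts uncertain.

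One DXp library lacked the collagen IV genes of the basement membrane. Col4a1 had 0 counts and Col4a2 4 counts in DXp replicate 1, against 51355 and 8241 counts in replicate 2. In WT_EV Col4a1 had 92225 to 284971 counts and in DXp_DXm 23204 and 79443. The neighbouring genes share a promoter region on chromosome 8. Neither gene passed in DXp (adjusted p 0.360 and 0.152).

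Some marker genes of other cell types had few or no counts. The pluripotency factor gene Pou5f1 had 3 to 12 counts in WT_EV and 0 in the deletion libraries, Nanog had 8 and 10 counts in DXp_DXm and 2 or fewer in the other WT_EV and deletion libraries, and Sox2 had 1 count in 1 WT_clone library and none in the others. The fibroblast collagen gene Col1a1 had at most 1 count in the 7 libraries and Col3a1 had none in the 9 libraries. Of 9 tested pluripotency genes, 1 rose and 6 fell in DXp, of 5 trophoblast genes 1 rose and 2 fell, of 4 fibroblast genes 1 rose and 1 fell, and of 9 germline genes 6 rose and 2 fell. Of these lists, 7, 3, 2 and 8 genes passed when adjusted over the list alone. With offsets 2 pluripotency genes rose and 2 fell, 2 trophoblast genes rose and 2 fell, 2 fibroblast genes rose, and 3 germline genes rose.

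Among cell-state lists in DXp, 7 of 13 interferon genes rose and 4 fell, and 12 passed when adjusted over the list alone. In DXp_DXm the interferon-induced gene Oasl2 rose to 9.84 ± 4.91 CPM (n = 2), log2 2.30 (SE 0.46, adjusted p 0.00150). Of 20 p53 targets 10 rose and 8 fell, of 19 cholesterol genes 5 rose and 9 fell, and of 21 lysosome and endocytosis genes 7 rose and 10 fell. Of 13 TGF-beta and BMP genes 4 rose and 2 fell. Of these lists, 18, 14, 17 and 5 genes passed when adjusted over the list alone. With offsets 6 p53 targets rose and 3 fell, 2 cholesterol genes rose and 9 fell, 6 lysosome and endocytosis genes rose and 5 fell, 7 TGF-beta and BMP genes rose and 1 fell, and 5 interferon genes rose. None of these lists passed with camera. Median, mean and camera direction differed in sign in DXp for polycomb, p53, early stress and fibroblast genes. They did so in DXp_DXm for cell cycle, polycomb, p53, trophoblast and WNT genes, and between the deletions for interferon, p53, primitive endoderm and trophoblast genes.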
